A study of Homo sapiens with 6 samples.

How the data were processed

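RNA of MCF-10A cells in 3D culture was measured on 6 one-colour arrays, with 2 arrays on each of days 4, 8 and 12. Samples were grouped by the day in their titles. Per the labels' protocols, Cy3-labelled cRNA was prepared from total RNA with a one-colour amplification kit. Per the file headers, the deposited scanner files hold spot intensity values from Agilent Feature Extraction 9.5.3.1, while the submitters' processing notes name version 11.5.1. The processed intensity was background-subtracted and detrended within each array, per the file headers, and was not normalized between arrays. Each array held 45015 spots, of which 43376 were non-control spots for 41000 probes. The deposited value table is on a log2 scale, and each probe in it is centred on its median over the 6 arrays. How the authors scaled it between arrays is not stated. It holds 41078 rows, 41000 of which matched a non-control probe, and its column medians were -0.19 and -0.24 on day 4, 0.02 and -0.01 on day 8 and 0.06 and 0.02 on day 12. Differences between arrays in this table had slopes of 1.00 against the scaled scanner values, and r was at least 0.9999 across probes well above background on all 6 arrays. Its scale and direction are thus known and its scaling constant is not.

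The log2 of the processed signal had each array's 75th percentile over non-control spots subtracted. Spots marked as non-uniform or population outliers were left out, and spots of 1 probe were averaged. A probe was tested if it had a value on all 6 arrays and was well above background on both arrays of at least 1 day, which left 26453 probes. For each gene name the tested probe with the highest mean stood for the gene, which gave 19400 genes, 5289 of them with several tested probes. Gene names are those of the files, updated through accessions where the reference table of gene names held them, which matched 23958 probes. In all 28372 probes had a gene symbol and 12628 did not. Probe positions are those of the files, on hg18. A probe that was not well above background on either array of a day has only a bound there. Its fold is given as at least the bright day's mean over the dim day's mean of, per array, the higher of the probe's own signal and the lowest signal among probes well above background.

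Tests used limma 3.58.1 in R 4.3.3 with 1 mean per day over all 6 arrays and empirical Bayes moderation. Day 8 was compared with day 4, day 12 with day 8 and day 12 with day 4. A moderated F-test covered the 3 days, and the difference between the 2 intervals was tested as a contrast of its own. P-values were adjusted by the Benjamini-Hochberg method over all genes, with a threshold of 0.05. Gene lists, 41 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. The test with an estimated correlation rests on only 3 residual degrees of freedom. It can thus miss shifts that the preset correlation calls, also where the members hardly correlate. The number of arrays limits the precision, with a median SE of 0.07 on the log2 scale.

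The genes named were chosen by a rule fixed before the data were examined. It took, per comparison, the 8 largest rises and 8 largest falls that passed, had a gene symbol and whose arrays did not overlap. It also took up to 4 members with the smallest p from each list that passed or had at least 3 changed members, and 12 markers whatever their result (MKI67, CCNB1, CDKN1B, BCL2L11, LAMB3, COL4A1, ITGB4, KRT14, KRT18, CDH1, GAPDH and ACTB). Some genes that this rule selects are not reported here, and no others took their place.

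Per the file headers, slide 1 held replicate 1 of every day and slide 2 replicate 2, each slide with its own scan, and the position on a slide was the same for a day on both slides. The slide block and the replicate block are therefore 1 fit, and the layout does not separate position on the slide from day. Only an effect of position on the spots themselves can be examined, and only in part, through the means of the spike-in probes' spots. The alternatives were quantile normalization, median scaling, normexp background correction with an offset of 50, the deposited value table, no filter and a stricter filter on dim probes, outlier spots kept, the mean of a gene's probes, an intensity trend, robust moderation, the replicate block, leaving out each array, only the 4 arrays compared, a fold minimum of 2 and a threshold of 0.01. Scaling to the mean of the E1A spike-in probes with signals over 50, and normexp without spots whose local background was over 2 times the array's median, were chosen after seeing the data.

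The fit was tested on simulated data with 19400 genes, 200 of them changed. Of 50 genes changed 1.25-fold it recovered 0%, 4% and 2% in the 3 comparisons. For day 8 against day 4 it recovered 28% of 50 genes changed 1.5-fold, 62% of those changed 2-fold and 80% of those changed 4-fold, and 1.16% of its calls were false. For day 12 against day 8 the shares were 38%, 68% and 94%, with 8.93% false, and for day 12 against day 4 they were 42%, 76% and 86%, with 4.63% false. Each share comes from a single run. The data held far more changed genes, with 14578, 8295 and 14692 called, and the adjusted p depends on their share. Log2 changes as small as 0.11, 0.13 and 0.11 were called in the data, so the simulated shares do not carry over to it.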

Results

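MCF-10A is an established line of normal-like human mammary epithelial cells that form hollow, polarised acini when grown in basement membrane gel. Gene expression was measured in such cultures on days 4, 8 and 12, to follow how it changed while acini formed. Each day had 2 one-colour arrays, so 6 arrays entered the comparisons. The labels do not say whether the 2 arrays of a day came from separate cultures, so the p-values measure the spread between these arrays, which may be technical. Between 61.2% and 66.2% of the spots on an array were well above background, and no probe was saturated. The 75th percentile of the signal was 593 and 605 on day 4, 390 and 397 on day 8, and 377 and 381 on day 12. After scaling to that percentile, the 2 arrays of a day had a Pearson correlation across genes of 0.996 to 0.997. Across genes, day 4 and day 8 correlated at 0.936 to 0.938 and day 8 and day 12 at 0.982 to 0.988. In total 19400 genes were tested. Levels below are log2 signals relative to the 75th percentile of the array, and log2 fold changes are given ± SE of the fit with n = 2 arrays per day.

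Between day 4 and day 8, the genes of cell division fell together. Of 45 measured genes of mitosis and the G2/M phase, 44 fell and none rose, with the same counts when adjusted over the list alone, and the list's median log2 change was -4.64, or -4.49 with dim genes at their bound. Among them CEP55, which acts in the last step of cell separation, changed by -6.01 ± 0.05 (adjusted p = 1.46e-05), PRC1, a spindle midzone protein, by -3.46 ± 0.04, and NDC80, a kinetochore protein, by -4.64 ± 0.05. Of 52 genes of DNA replication, 50 fell and 1 rose, counts that were the same when adjusted over the list alone, with a median of -2.39. CDC7, a replication kinase, changed by -3.47 ± 0.05. Camera gave adjusted p = 7.70e-18 for mitosis and 7.51e-17 for replication. With an estimated correlation these became adjusted p = 0.578 and adjusted p = 0.540. That test has only 3 residual degrees of freedom, so such values do not measure the effect of correlation between genes alone. The mitosis median was -4.62 on slide 1 and -4.65 on slide 2.

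Genes of cell cycle exit and quiescence rose over the same interval. Of 30 measured members, 27 rose and 2 fell, also when adjusted over the list alone, with a median of 1.18, against 16, 6 and 0.26 under spike-in scaling (camera adjusted p = 1.67e-05, and adjusted p = 0.578 with an estimated correlation). BTG1, an antiproliferative factor, rose by 2.89 ± 0.06 and TXNIP, an inhibitor of thioredoxin, by 3.25 ± 0.08. CDKN1B, which encodes the cyclin-dependent kinase inhibitor p27, rose by 1.16 ± 0.06 (adjusted p = 7.96e-05), or by 0.24 under spike-in scaling. CCNB1, the mitotic cyclin B1, fell from 4.11 ± 0.04 to -0.29 ± 0.03 (mean ± SD, n = 2), a log2 change of -4.39 ± 0.07. The single MKI67 probe read -4.12 and -4.17 on day 4 and was not well above background on either day 8 array, a difference of at least 2.53-fold that did not pass the test (adjusted p = 0.129). It passed when either day 12 array was left out (adjusted p = 0.000188), because the 2 day 12 arrays lay apart for MKI67 and all 6 arrays share 1 estimate of the spread.

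Biosynthetic genes moved in both directions. Cholesterol synthesis fell in 24 of 25 members and rose in 1, also when adjusted over the list alone, with a median of -1.54 (camera adjusted p = 1.71e-09, and adjusted p = 0.501 with an estimated correlation). HMGCS1, an early enzyme of that pathway, changed by -3.31 ± 0.05. Ribosome biogenesis and MYC targets fell in 37 of 40 members and rose in 1, with the same counts when adjusted over the list alone and a median of -0.94 (adjusted p = 3.32e-10, and adjusted p = 0.578 with an estimated correlation). ODC1, which makes polyamines, changed by -2.60 ± 0.07. Oxidative phosphorylation fell in 28 of 38 members and rose in 5, with the same counts adjusted over the list alone and a median of -0.40, against 0 higher, 38 lower and -1.32 under spike-in scaling (adjusted p = 4.67e-05, and adjusted p = 0.578 with an estimated correlation). Fatty acid synthesis and lipid droplet genes fell in 19 of 30 members and rose in 8, or 20 and 8 adjusted over the list alone, with a median of -0.52 (adjusted p = 0.0134, 0.428 under spike-in scaling with a larger fall of -1.44, and adjusted p = 0.578 with an estimated correlation). Cytoplasmic ribosomal protein genes rose in 48 of 48 members, also adjusted over the list alone, with a median of 0.73 (adjusted p = 1.71e-09, and adjusted p = 0.578 with an estimated correlation), but 3 rose and 26 fell, with a median of -0.19, when arrays were scaled to the spike-in probes instead.

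Immune and hormone-responsive genes rose between day 4 and day 8 under the main scaling, by much less under spike-in scaling. Interferon response genes rose in 36 of 45 members and fell in 4, or 37 and 4 adjusted over the list alone, with a median of 1.09, against 20, 16 and 0.17 under spike-in scaling (camera adjusted p = 6.42e-05, and adjusted p = 0.631 with an estimated correlation). IRF9, a transcription factor of interferon signalling, rose by 2.75 ± 0.09. Cytokines, chemokines and NF-kB targets rose in 22 of 32 members and fell in 7, or 23 and 7 adjusted over the list alone, with a median of 1.23, against 17, 13 and 0.31 under spike-in scaling (adjusted p = 0.0105, and adjusted p = 0.697 with an estimated correlation). Without the filter on dim probes that list did not pass (median 0.67, adjusted p = 0.0932). SAA1, an acute-phase protein gene, rose by 3.98 ± 0.06 and SOD2, the mitochondrial superoxide dismutase gene, by 3.40 ± 0.06. Glucocorticoid targets rose in 17 of 24 members and fell in 3, or 18 and 3 adjusted over the list alone, with a median of 1.02, against 12, 10 and 0.10 under spike-in scaling (adjusted p = 0.00687, and adjusted p = 0.578 with an estimated correlation). TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein, rose by 3.00 ± 0.06. Autophagy and lysosome genes rose in 26 of 41 members and fell in 7, also adjusted over the list alone, with a median of 0.40 under the main scaling, against 9 higher, 24 lower and -0.52 under spike-in scaling (adjusted p = 0.0347, and adjusted p = 0.578 with an estimated correlation). That call was also lost at a median of 0.40 without the filter on dim probes (adjusted p = 0.133) and with the stricter filter (0.0569), with normexp on all spots (0.924, median 0.18) or without the 5 spots (0.375, 0.41), and without day 8 replicate 1 (0.0520, 0.37).

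The largest single changes from day 4 to day 8 included complement and division genes. GPNMB, a transmembrane glycoprotein gene, rose 793-fold from -4.04 ± 0.04 to 5.59 ± 0.06 (mean ± SD, n = 2, adjusted p = 1.46e-05). Its probe A_23_P134426 lies on chromosome 7 at 23281021 to 23281080 of hg18. C1R and C1S, the proteases that start the classical complement pathway, rose 190-fold and 150-fold, with probes on chromosome 12 at 7057822 to 7057881 and 7048354 to 7048413. CFB, complement factor B, rose 87.9-fold. SAA4 rose at least 106-fold and AGT, which encodes angiotensinogen, at least 39.4-fold, since their probes were not well above background on day 4. LRRC2 rose 86.7-fold on 1 probe, while its 2 other probes were not well above background on any array. SPC25, a kinetochore gene, fell at least 199-fold. Its probe A_23_P51085 lies on chromosome 2 at 169436202 to 169436261. RRM2, a subunit of ribonucleotide reductase, fell at least 69.7-fold, CCNA2 (cyclin A2) at least 82.1-fold, MCM10 at least 31.6-fold and ESCO2 at least 25.1-fold. CDC45 fell 96.1-fold, FGFBP1 73.2-fold and DLGAP5 71.9-fold.

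In all, 14578 genes changed from day 4 to day 8 (75.1% of those tested), 8223 upward and 6355 downward. Of these, 2666 were higher and 2486 lower by at least 2-fold, against 822 higher of 8635 under spike-in scaling and 1632 higher of 3015 with normexp without 5 high-background spots. The 2 arrays of one day lay wholly above those of the other for 88.7% of genes, where chance gives 33.3%. The median log2 change of all genes was 0.12 under the main scaling and -0.80 under spike-in scaling, which called 2050 genes higher and 14145 lower. Spike-in scaling moves the log2 change of every gene by the same -0.92 here, so that GPNMB, C1R, C1S and CFB rose by 8.71, 6.65, 6.31 and 5.54 under it. Normexp background correction called 2519 genes, because 5 spots with a high local background on 1 array distorted its fit, and it called 16070 without those spots.

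**Figure D1:**
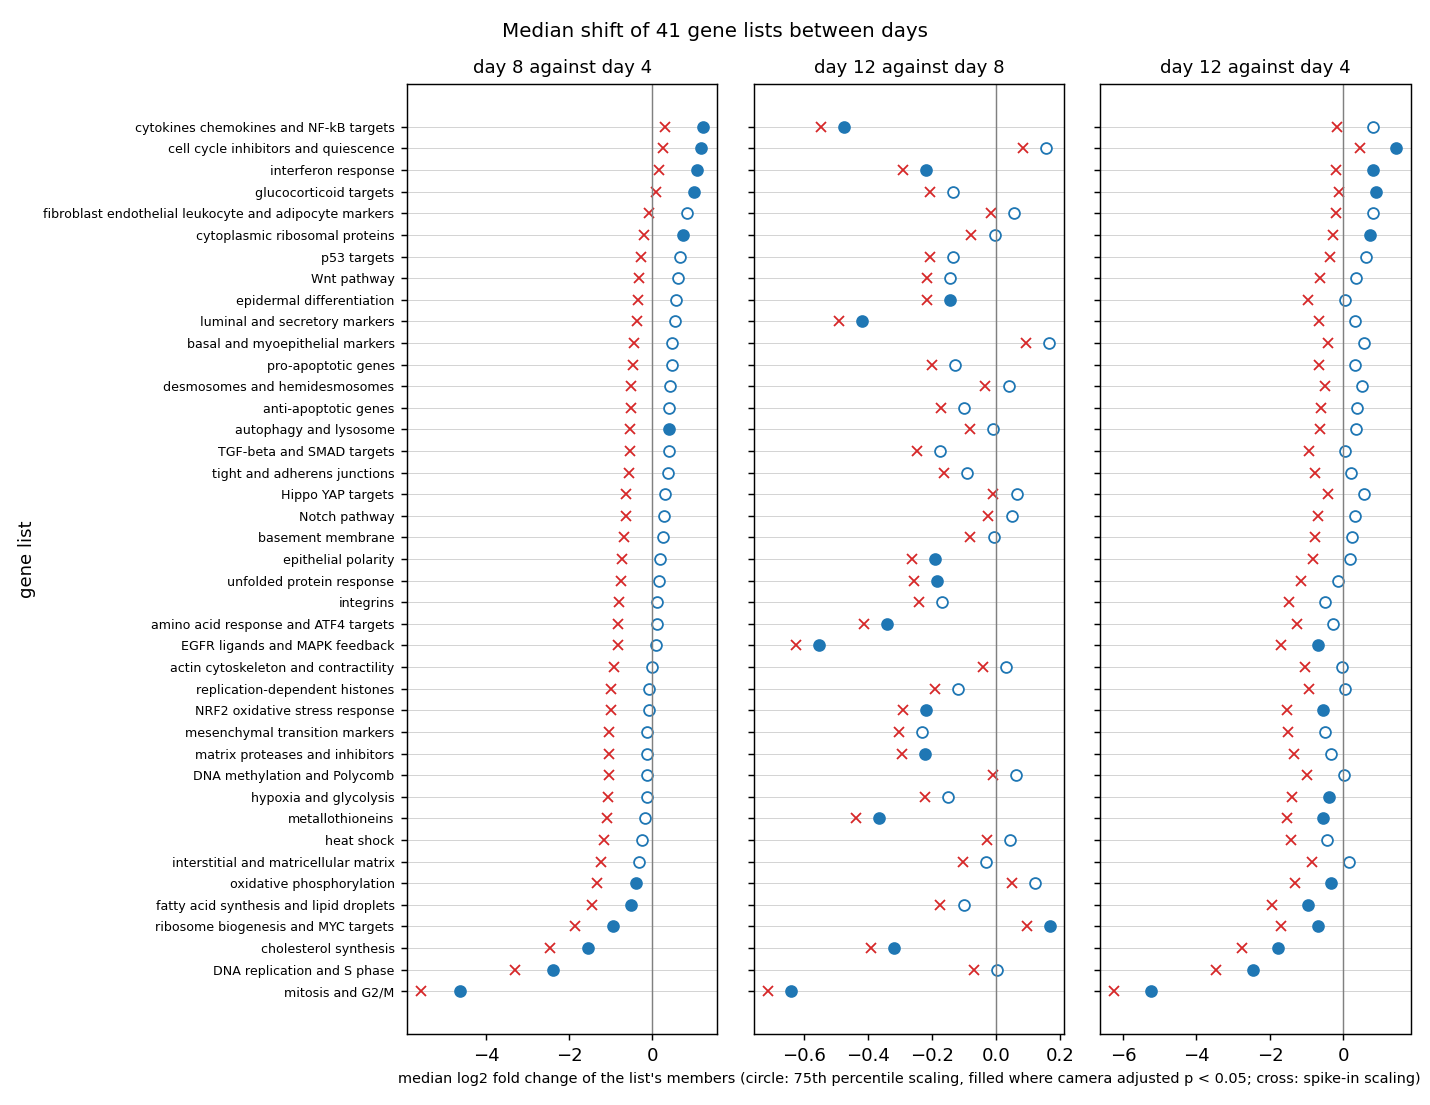
Median log2 fold change of each of 41 gene lists (rows) in the 3 comparisons between days, with circles for the main scaling, filled where camera passed, and crosses for spike-in scaling. The mitosis list had the lowest median from day 4 to day 8, at -4.64, and ribosomal proteins had 0.73 under the main scaling but -0.19 under spike-in scaling.

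From day 8 to day 12, EGFR and MAPK feedback genes fell, as did 4 lists of stress responses, while heat shock genes (median 0.04, or -0.03 under spike-in scaling, adjusted p = 0.716), hypoxia and glycolysis genes (-0.15, 0.0852) and p53 targets (-0.13, 0.0538) did not pass. EGFR ligands and MAPK feedback genes fell in 26 of 38 members and rose in 2, or 27 and 2 adjusted over the list alone, with a median of -0.55 (camera adjusted p = 1.46e-07, and adjusted p = 0.434 with an estimated correlation). DUSP6, a phosphatase that limits ERK, changed by -2.74 ± 0.17 (adjusted p = 0.00191) and DUSP5 by -1.49 ± 0.07. The list's median was -0.50 on slide 1 and -0.64 on slide 2. ATF4 targets of the amino acid response fell in 19 of 32 members and rose in 4, or 19 and 5 adjusted over the list alone, with a median of -0.34 (adjusted p = 0.000164, and adjusted p = 0.434 with an estimated correlation). ASNS, asparagine synthetase, changed by -0.98 ± 0.04. NRF2 targets fell in 16 of 31 members and rose in 2, or 17 and 2 adjusted over the list alone, with a median of -0.22 (adjusted p = 0.000164, and adjusted p = 0.546 with an estimated correlation). Unfolded protein response genes fell in 12 of 25 members and rose in 1, or 13 and 1 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.000425, and adjusted p = 0.546 with an estimated correlation). Metallothionein genes fell in 9 of 13 members and rose in 0, also adjusted over the list alone, with a median of -0.37 (adjusted p = 0.00209, and adjusted p = 0.546 with an estimated correlation).

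Cytokine and NF-kB targets, which had risen by day 8, fell in 19 of 32 members and rose in 3, also adjusted over the list alone, with a median of -0.48 (adjusted p = 0.000431, and adjusted p = 0.595 with an estimated correlation). Interferon response genes fell in 21 of 45 members and rose in 9, or 22 and 9 adjusted over the list alone, with a median of -0.22 (adjusted p = 0.00491, and adjusted p = 0.656 with an estimated correlation). IFITM1, an antiviral membrane protein gene, changed by -1.91 ± 0.15. Mitosis genes fell further in 32 of 45 members and rose in 0, also adjusted over the list alone, with a median of -0.64 (adjusted p = 1.59e-09, and adjusted p = 0.595 with an estimated correlation). Cholesterol synthesis fell in 14 of 25 members and rose in 3, also adjusted over the list alone, with a median of -0.32 (adjusted p = 0.000896, and adjusted p = 0.434 with an estimated correlation). Ribosome biogenesis and MYC targets went the other way, rising in 19 of 40 members and falling in 2, or 20 and 2 adjusted over the list alone, with a median of 0.17, against 10 higher, 3 lower and 0.10 under spike-in scaling (adjusted p = 0.00425, and adjusted p = 0.635 with an estimated correlation).

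Luminal and secretory markers fell from day 8 to day 12 in 13 of 26 members and rose in 3, or 14 and 3 adjusted over the list alone, with a median of -0.42 (adjusted p = 0.00215, and adjusted p = 0.546 with an estimated correlation). Among genes well above background on all 6 arrays their median was -0.18 and they did not pass (adjusted p = 0.0743). WFDC2, a secreted protease inhibitor gene, changed by -1.58 ± 0.05. Epidermal differentiation genes fell in 11 of 29 members and rose in 4, also adjusted over the list alone, with a median of -0.15 (adjusted p = 0.0175, and adjusted p = 0.434 with an estimated correlation). S100A9 changed by -2.20 ± 0.19. Matrix proteases and inhibitors fell in 12 of 26 members and rose in 2, or 13 and 3 adjusted over the list alone, with a median of -0.22 (adjusted p = 0.00520, and adjusted p = 0.434 with an estimated correlation). PLAU, the urokinase gene, changed by -1.79 ± 0.15, while TIMP3, an inhibitor of metalloproteases, rose by 1.34 ± 0.07. Epithelial polarity genes fell in 14 of 28 members and rose in 5, or 15 and 5 adjusted over the list alone, with a median of -0.19 (adjusted p = 0.00925, and adjusted p = 0.646 with an estimated correlation). LAMB3, a laminin-332 chain gene, changed by -1.36 ± 0.15, and CDH1, which encodes E-cadherin, by -1.05 ± 0.08 (adjusted p = 0.00239). Tight and adherens junctions (median -0.09, adjusted p = 0.202), basal and myoepithelial markers (0.16, 0.321), desmosomes and hemidesmosomes (0.04, or -0.03 under spike-in scaling, 0.819) and mesenchymal transition markers (-0.23, 0.133) did not pass.

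Among named genes well above background on both arrays of both days, the largest single fall from day 8 to day 12 was that of CHI3L1. This secreted chitinase-like protein gene fell 17.6-fold (adjusted p = 0.00176). FBLN2, a matrix protein gene, fell at least 7.10-fold, SLC27A2 at least 7.87-fold, LHFPL5 at least 5.58-fold, SNX31 at least 5.00-fold and IQGAP2 at least 3.24-fold. UBD, a ubiquitin-like protein gene, changed by -3.46 ± 0.32. SYT17 changed by -3.80 ± 0.49, with 1 of its 2 day 12 arrays well above background. SLC2A5, the fructose transporter gene, rose 16.1-fold, and MYOT and TDRD9 rose 10.9-fold and 5.52-fold. RBP4, a retinol carrier gene, rose at least 9.81-fold, ABI3BP at least 3.07-fold and MGC39545 at least 1.38-fold. LKAAEAR1 rose at least 1.61-fold, with 1 of its 2 day 12 arrays well above background. The call for LKAAEAR1 was lost when either day 8 array was left out, at an unchanged log2 change of 2.72 and 2.71.

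In all, 8295 genes changed from day 8 to day 12 (42.8%), 4624 upward and 3671 downward, and 1063 of them by at least 2-fold, against 242 with normexp without the 5 spots and 693 of the genes well above background on all 6 arrays. The median log2 change of all genes was 0.02 under the main scaling and -0.05 under spike-in scaling, which called 3179 genes higher and 4461 lower and moves every gene by -0.07. Leaving out day 8 replicate 1 gave 4966. Normexp called 0 genes with all spots and 6422 without the 5 spots. The 2 intervals differed for 12526 genes by a limma test of the difference itself. Among genes past the threshold in both intervals, 2072 rose then fell, 2342 fell then rose, 1431 rose in both and 1008 fell in both. Independent lists of these sizes would share 1556, 1515, 1960 and 1203 genes. All these counts are those of the main scaling. Spike-in scaling called only 2050 genes higher and 14145 lower from day 4 to day 8, so the patterns depend on the scaling. In 20 simulations of unchanged groups the 2 intervals correlated across genes at -0.502 on average, since they share day 8, and here at -0.195. The simulated groups held no true change, so -0.502 is no benchmark here. At most 1 gene was called in them from day 4 to day 8, and 0 in opposite directions. With no true change hardly any call can pass, so these counts do not show how many opposite calls noise adds here. The log2 changes in these data had SDs of 1.17 and 0.53 across genes, against a median SE of 0.07. Noise between the day 8 arrays was thus small beside the changes. That argues against such noise as the main source of the excess of opposite directions under the main scaling. A deviation that both day 8 arrays share would have the same effect and was not tested.

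Over the whole period, from day 4 to day 12, the fall of division genes was the largest group change. Mitosis genes fell in 44 of 45 members, also adjusted over the list alone, with a median of -5.24, or -4.88 with dim genes at their bound (camera adjusted p = 6.94e-20, and adjusted p = 0.544 with an estimated correlation). The median was -4.93 on slide 1 and -5.55 on slide 2. DNA replication genes fell in 50 of 52 members and rose in 1, also adjusted over the list alone, with a median of -2.47 (adjusted p = 2.60e-18, and adjusted p = 0.483 with an estimated correlation). TK1, thymidine kinase, changed by -6.62 ± 0.09. Cholesterol synthesis fell in 24 of 25 members, also adjusted over the list alone, with a median of -1.77 (adjusted p = 2.84e-11, and adjusted p = 0.378 with an estimated correlation). INSIG1, a sterol sensor gene, changed by -4.06 ± 0.05. Fatty acid synthesis and lipid droplet genes fell in 19 of 30 members and rose in 7, or 20 and 7 adjusted over the list alone, with a median of -0.95 (adjusted p = 0.00144, 0.486 under spike-in scaling with a larger fall of -1.95, and adjusted p = 0.544 with an estimated correlation). FADS2, a fatty acid desaturase gene, changed by -3.97 ± 0.04.

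Ribosome biogenesis and MYC targets were lower on day 12 than on day 4 in 38 of 40 members and higher in 2, also adjusted over the list alone, with a median of -0.69 (adjusted p = 3.52e-10, and adjusted p = 0.544 with an estimated correlation). Oxidative phosphorylation fell in 26 of 38 members and rose in 4, also adjusted over the list alone, with a median of -0.32, against 0 higher, 38 lower and -1.32 under spike-in scaling (adjusted p = 0.000317, and adjusted p = 0.551 with an estimated correlation). NRF2 targets fell in 20 of 31 members and rose in 5, or 21 and 5 adjusted over the list alone, with a median of -0.55, against 0 higher, 30 lower and -1.54 under spike-in scaling (adjusted p = 0.000436, and adjusted p = 0.544 with an estimated correlation). NQO1, a quinone reductase gene, changed by -3.01 ± 0.05. Hypoxia and glycolysis genes fell in 22 of 34 members and rose in 9, also adjusted over the list alone, with a median of -0.40 (adjusted p = 0.0222, 0.314 under spike-in scaling with 4 higher, 29 lower and a larger fall of -1.39, and adjusted p = 0.551 with an estimated correlation). ADM, the adrenomedullin gene, rose by 2.16 ± 0.06 against the direction of that list. Metallothioneins fell in 9 of 13 members and rose in 2, and EGFR ligands and MAPK feedback genes fell in 22 of 38 and rose in 12, each also adjusted over the list alone. Their medians were -0.54 and -0.70, with camera adjusted p = 0.0345 for both and adjusted p = 0.551 with an estimated correlation for both. The EGFR call was lost with quantile normalization (adjusted p = 0.0575, median -0.69), median scaling (0.0629, -0.79), the stricter filter (0.146, -0.25) and spike-in scaling (0.827, -1.69), and the metallothionein call with the mean of probes (0.162, -0.55) and spike-in scaling (0.266, -1.54). The stricter filter made the EGFR fall much smaller and quantile normalization left it nearly the same, while the other settings listed here made the falls larger.

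Cell cycle inhibitors and quiescence genes were higher on day 12 than on day 4 in 27 of 30 members and lower in 2, also adjusted over the list alone, with a median of 1.45, against 18, 5 and 0.45 under spike-in scaling (adjusted p = 8.85e-06, and adjusted p = 0.544 with an estimated correlation). FOXO1, a transcription factor restrained by AKT, rose by 2.18 ± 0.05. Ribosomal protein genes rose in 48 of 48 members, also adjusted over the list alone, with a median of 0.72 under the main scaling, against 1 higher, 36 lower and -0.27 under spike-in scaling (adjusted p = 5.75e-09, and adjusted p = 0.551 with an estimated correlation). Interferon response genes rose in 34 of 45 members and fell in 4, also adjusted over the list alone, with a median of 0.81 under the main scaling, against 15 higher, 23 lower and -0.19 under spike-in scaling (adjusted p = 0.00140, and adjusted p = 0.606 with an estimated correlation). Glucocorticoid targets rose in 18 of 24 members and fell in 5, also adjusted over the list alone, with a median of 0.89 under the main scaling, against 9 higher, 11 lower and -0.10 under spike-in scaling (adjusted p = 0.0345, and adjusted p = 0.551 with an estimated correlation). That call was lost without the filter on dim probes (adjusted p = 0.0802, median 0.95), with the stricter filter (0.0588, 0.84) and with normexp without the 5 spots (0.110, 0.81). ZBTB16 rose by 2.44 ± 0.04. Cytokine and NF-kB targets had a median of 0.82 under the main scaling and -0.18 under spike-in scaling and did not pass (adjusted p = 0.0905).

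Among single genes, SHCBP1 fell at least 44.4-fold, KIF20A, a mitotic kinesin gene, at least 104-fold and DLGAP5 at least 124-fold from day 4 to day 12, and PLK1, a mitotic kinase gene, fell 162-fold. GPNMB was 347-fold higher, CFAP61, a cilium protein gene, 77.6-fold, CHI3L2 62.3-fold and SLC2A14 62.2-fold. BCL2L11, which encodes the pro-apoptotic protein BIM, rose by 2.22 ± 0.04 from day 4 to day 8 and was 2.16 ± 0.04 higher on day 12 than on day 4 (adjusted p = 1.77e-05). From day 8 to day 12 it changed by -0.06 on that probe (limma adjusted p = 0.301). With the mean of its 4 tested probes it changed by -0.37 and passed (adjusted p = 0.00853). The list of pro-apoptotic genes did not pass in either comparison with day 4, with medians of 0.47 and 0.33 under the main scaling, -0.46 and -0.67 under spike-in scaling, and adjusted p = 0.246 and 0.539. ITGB4, the integrin beta 4 gene, was 1.09 ± 0.07 higher under the main scaling but only 0.10 higher under spike-in scaling, where it did not pass (adjusted p = 0.189), and COL4A1, a collagen IV gene, changed by -1.61 ± 0.09. Basement membrane genes as a list did not pass (median 0.23, or -0.76 under spike-in scaling, adjusted p = 0.539), nor did integrins (median -0.50, or -0.22 with dim genes at their bound, adjusted p = 0.479). KRT14, a basal keratin gene, changed by -1.44 ± 0.14 and KRT18, a luminal keratin gene, by -0.88 ± 0.06. The reference genes moved as well, since ACTB changed by -0.89 ± 0.06 and GAPDH by -0.26 ± 0.06. Spike-in scaling lowers both further by its construction, so it is no separate support. The GAPDH call was lost when either day 4 array was left out, at changes of -0.252 without replicate 1 and -0.259 without replicate 2. MKI67 had a day 12 mean of -4.93 ± 3.61 (SD, n = 2), because its single probe read -7.49 on one array and -2.38 on the other, and it did not pass (adjusted p = 0.691).

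**Figure D2:**
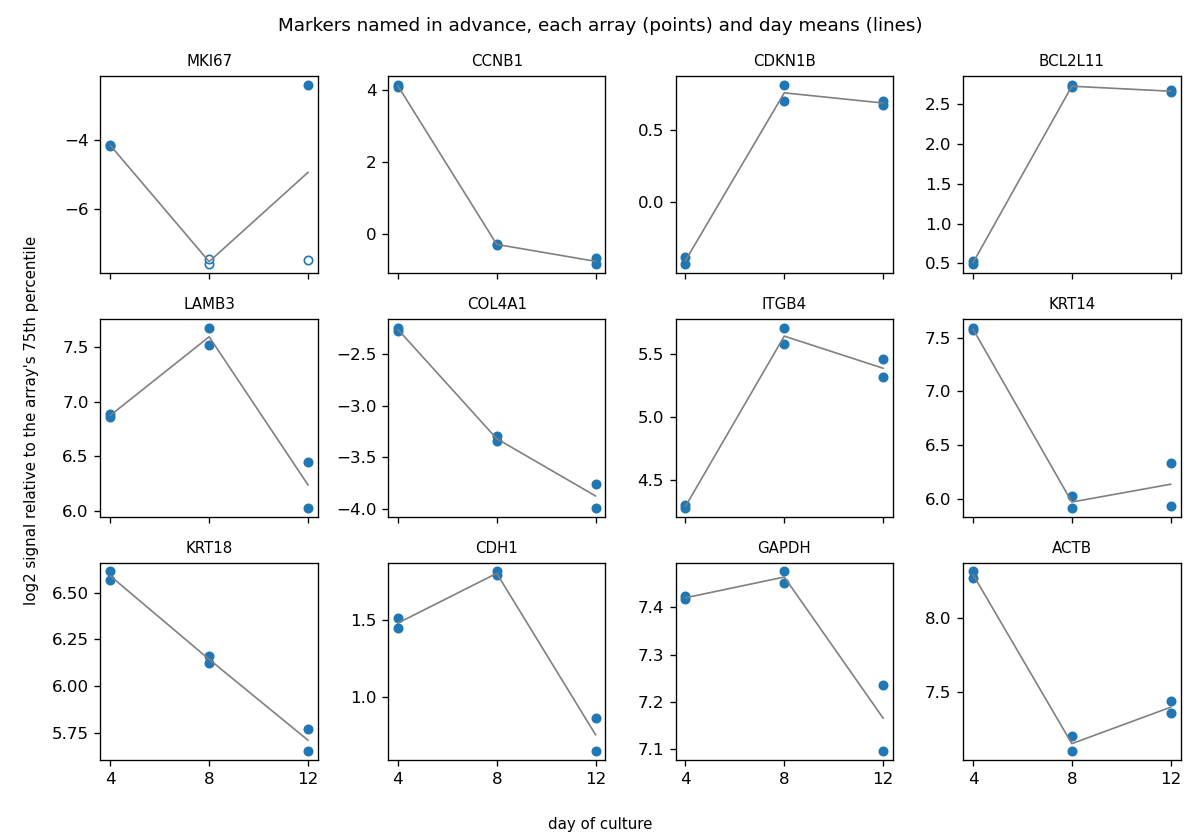
Log2 signal relative to the array's 75th percentile for the 12 markers named in advance, by day of culture, with 1 point per array, open where the probe was not well above background, and lines through the day means. CCNB1 fell from 4.11 on day 4 to -0.29 on day 8, and the 2 arrays of day 12 lay apart for MKI67, at -7.49 and -2.38.

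In all, 14692 genes differed between day 12 and day 4 (75.7%), with 8621 higher and 6071 lower, and 5035 of them by at least 2-fold, against 8772 under spike-in scaling and 2941 with normexp without the 5 spots. The median log2 change of all genes was 0.17 under the main scaling and -0.83 under spike-in scaling, which called 1886 genes higher and 14540 lower and moves every gene by -0.99. Normexp called 1899 genes with all spots and 16208 without the 5 spots. A moderated F-test over the 3 days passed for 16010 genes, and for 1817 with normexp on all spots. Among genes with several tested probes, 8.11% had probes called in opposite directions from day 4 to day 8 and 9.47% from day 4 to day 12.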

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

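The early and the late interval differed for 12526 genes by the limma test of that difference. The tests of the summed signal and of the 2 slides below were chosen only after values that bear on them had been seen.

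Against the spike-in probes, the median gene was lower on day 8 than on day 4, by -0.80 on the log2 scale. A few very bright genes taking more of the labelled RNA would by itself leave the summed signal over the spike-in signal level. That sum changed by -0.58, against gaps of at most 0.03 between arrays of a day, so this cannot be the whole cause. The brightest 100 spots held 19.3% and 19.0% of the signal on day 4 and 21.9% and 21.5% on day 8, so a partial share in the fall is not excluded. The spike-in probes shifted by nearly 1 constant, with a range of 0.11 across probes. Such a constant is what a different amount of spike-in or labelling yield gives, and also what less messenger RNA per total RNA on day 8 gives, so these cannot be told apart here. The labels name the day as the design's own difference, and it stays open.

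In all 5152 genes changed by at least 2-fold between day 4 and day 8. An effect of array position on the spots could also scatter the spike-in probes. The SD of their changes was 0.0312 times that of the genes. Each spike-in value was a mean over that probe's spots, however, while most gene probes had a single spot. Averaging evens out scatter between spots, so the low ratio cannot exclude an effect of position. It also does not bear on any step before labelling. The changes correlated at 0.949 across genes between the 2 slides, so no single slide carried them. Probes not well above background cannot be the whole cause either. Among genes well above background on all 6 arrays, the share changed at least 2-fold was 0.907 times the share among all genes. Probes in that subset can still be dim, so it does not exclude low signal as a source of large folds. Normexp with its offset, without the high-background spots, left 3015 genes changed at least 2-fold, against 5152. A part for low signal thus stays open. The day of culture, which the design names, was not tested apart from these and stays open.

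CD86, PPP6R1, LRRC2, RPA4 and CABP7 rose together, a set picked after its values were seen, by 5.63 for CABP7 to 6.44 for LRRC2 on the log2 scale from day 4 to day 8. Other tested probes of these genes, 2 in number, had a median change of 0.32, so the rising probes may bind another transcript. The second PPP6R1 probe, well above background on all 6 arrays, changed by 0.14, and that of CD86 by 0.50. Transcript variants seen by 1 probe and not the other also remain open, and RPA4 and CABP7 had no second probe. No biological explanation was tested.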

How the results depend on the processing

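Spike-in scaling and normexp without 5 high-background spots were chosen after seeing the data. Normexp on all spots, as planned, gave 2519, 0 and 1899 changed genes (day 8 against 4, 12 against 8, 12 against 4), 1817 over the 3 days and 26 whose intervals differed. On day 8 replicate 2 those 5 spots had a local background of up to 12215, and the array's 5th percentile became 8.91 against 5.83 without them. Without them the counts were 16070, 6422, 16208, 17297 and 13228. A fold minimum of 2 left 5152, 1063 and 5035 genes, and a threshold of 0.01 left 4275 for day 12 against day 8. Leaving out 1 array gave 4966 to 6906 genes for that comparison, lowest without day 8 replicate 1, where the lone array is assumed to vary like the others. Lists passing went from 12, 14 and 14 to 0 with an estimated correlation, where 2, 4 and 2 had an unadjusted p under 0.05. That test has 3 residual degrees of freedom and so little power over 41 lists. ATF4 targets from day 8 to day 12 had an estimated correlation of 0.0007, under the preset 0.01. Their camera p still went from 1.6e-05 to 0.0164, so the lost calls do not measure correlation between genes alone. With fry, which tests each list by itself, 38, 30 and 37 lists passed. Without a filter on dim probes 24 lists passed for day 12 against day 8, and the cause was not tested. The other counts of changed genes and of passing lists, taken without a fold minimum, stayed within 1.5 times the main value. Of the calls given below as lost with direction kept, normexp on all spots accounts for 9 of 27 for lists and 54 of 92 for named genes.

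The replicate block, which is also the slide block, gave 14933, 8520 and 14967 changed genes and altered no list call and no named gene call. Deviations of same-numbered arrays correlated across genes at 0.08, 0.06 and 0.12. Such arrays shared a slide and its scan, and the labels do not say what else the numbers share. Across genes, the 2 slides' changes from day 8 to day 12 correlated at 0.756.

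Higher genes made up 56.4%, 55.7% and 58.7% of calls under the main scaling, 12.7% and 41.6% in the first 2 comparisons under spike-in scaling, with 1886 of 16426 in the last, 68.2%, 57.0% and 69.6% with normexp without the 5 spots and 67.6%, 56.2% and 69.9% without a filter. Of genes called under both scalings, 3761 and 4456 took opposite directions under spike-in scaling in the comparisons with day 4. That follows from its construction, a different constant per array.

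Spike-in scaling turned the medians of autophagy and lysosome (-0.52) and ribosomal proteins (-0.19) from day 4 to day 8, and of interferon response (-0.19), glucocorticoid targets (-0.10) and ribosomal proteins (-0.27) from day 4 to day 12. It turned LAMB3 (-0.20), CDH1 (-0.60) and GAPDH (-0.88) from day 4 to day 8, where quantile normalization also turned GAPDH (-0.52). Normexp on all spots turned the unfolded protein response (0.12), metallothioneins (0.059), ABI3BP (-0.42), LKAAEAR1 (-0.71), MGC39545 (-0.73), ITGB4 (0.15) and GAPDH (0.15) from day 8 to day 12, and COL4A1 (0.42) and CDH1 (-0.022) from day 4 to day 8. The mean of its probes turned COL4A1 (0.0759) from day 8 to day 12. MKI67 from day 4 to day 12 ranged from -3.34 without day 12 replicate 2 to 1.76 without day 12 replicate 1, since 1 spot on 1 array decides it. Among 760 values of lists that passed, 726 kept direction and call, 27 lost the call with direction kept and 7 turned. Turned values are counted apart, whether or not the call was also lost. Among 2588 values of the genes named here, 92 lost the call and 6 gained it with direction kept, and 13 turned. The other 2477 kept their call. Where a gene passed in neither setting, its direction was not compared. Among 10223 values of all genes the naming rule selects, 345 lost the call with direction kept and 50 turned. Of those that turned, 22 were under spike-in scaling and 20 with normexp on all spots. Between 48 and 53 genes per day had arrays over 2 log2 units apart, so single dim spots limit named genes near background.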

Other observations

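All tests in this part were chosen after the genes that prompted them were seen, and those genes and every member of the fixed lists were left out of them. Their predictions preceded the results.

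Genes of motile cilia, the beating cell projections, were examined because CFAP61, CFAP70 and ODAD4 rose from day 8 to day 12. Of 89 other members of a motile cilium list, only 28 were tested, so most of the list was not covered. Of these, 14 rose and 5 fell, with a median log2 change of 0.49. Camera gave p = 0.0113, and p = 0.0649 with an estimated correlation. For the genes tested, the hypothesis that motile cilium genes rise as a group may hold on the first test and missed the threshold on the second.

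Complement and acute-phase genes were examined because C1R, C1S, CFB, SAA4 and SERPINA3 rose from day 4 to day 8. Of 47 other members, 23 were tested, and 12 of these rose and 4 fell under the main scaling, with a median of 0.46. Spike-in scaling moves every gene by -0.92 in this comparison, which makes that median negative. Camera, on 2 arrays per day, gave p = 0.0976, and p = 0.165 with an estimated correlation. The prediction had taken a p of 0.05 or more as evidence against the hypothesis, which was a poor bound, since missing a threshold does not show that the genes stayed level. Whether the group rises may thus be left open.

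Alcohol, aldehyde and retinoid metabolism genes were examined because ALDH2, ADH1A, AOX1 and RBP4 were higher on day 12 than on day 4. Of 51 other members, 35 were tested, and 17 of these rose and 12 fell under the main scaling, with a median of 0.04. Spike-in scaling moves every gene by -0.99 in this comparison, which makes that median negative. Camera, on 2 arrays per day, gave p = 0.915, and p = 0.910 with an estimated correlation. The members went both ways, so the test gave no sign of a rise. Its prediction had the same poor bound, so a small rise is not excluded.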
